A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

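Genomic DNA was analysed from 2 pools of yeast colonies, 1 wild type and 1 rad52 deletion, each of about 10000 colonies carrying a new Ty3 marked with HIS3. Per the labels' protocols, DNA was digested with 3 restriction enzymes (Csp6I, HaeIII and HpyCH4V), circularised and amplified by inverse PCR from within Ty3, so that each read starts at the end of the 3′ LTR and runs into the flanking chromosome. The submitters' processing notes name Bowtie 0.9.8.1 and sacCer2 without stating their roles. Bowtie is an aligner, so the deposited alignments were taken to be made with it on that build. The rule for making clusters is not given in the sources used here.

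The deposited alignment files hold 1 line per alignment of a 19-base read, with single and multiple alignments in separate files, and no alignment has a mismatch. Read counts were obtained by counting lines of the deposited files per chromosome, strand and base, with no normalization. The authors' deposited cluster tables give counts of reads and of positions per cluster, strand and strain. For each cluster the authors also deposited the fraction of the strain's reads that it holds, headed as a percent in the file headers but on a scale of 0 to 1, which was not used for any result. The deposited tables further give signed distances to the nearest RNA polymerase III gene, coding gene and LTR, and box A and box B scores whose scale is not stated in the file headers.

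The first flanking base of a + read is the leftmost aligned base and that of a − read the rightmost. Ty3 duplicates 5 bp on insertion, so the flanks of both orientations at 1 site start 4 bp apart. The first base of each tRNA gene on sacCer2 was computed from the cluster edges and signed distances in the authors' deposited tables for 265 genes, and for tS(UGA)I from its sequence in the reads. For 69 genes with more than 1 cluster all clusters gave the same start. The first bases read matched those of other genes with the same anticodon for 226 of 232 genes off chromosome X. On chromosome X 2 of 19 matched, and 17 of 19 matched 1 bp to the right, so starts there are probably 1 bp off. The R64 gene table, which is of another assembly, was used only to count tRNA genes and those near each other, and none of its coordinates were set against positions on sacCer2. It lists 275 nuclear tRNA genes. The deposited tables name 267, of which 266 were placed.

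An insertion position is a chromosome, strand and first flanking base with at least 10 reads. It was counted near a tRNA gene within 100 bp of its first base on either side, and outside when more than 500 bp from every placed tRNA gene start and every other RNA polymerase III cluster in the deposited tables. Shares have Wilson 95% intervals and ratios of reads exact binomial 95% intervals. The enrichment used the highest aligned base of each chromosome as its length, which is below the true length, so it is a lower bound. Ratios of the strains are log2 ratios of shares of tRNA-gene reads. A list's median ratio was placed among those of 10000 random lists of the same size matched on mean reads. The libraries held 3034624 (wild type) and 3057512 (rad52 deletion) single-aligned reads. No test between strains was made, because each strain had 1 library.

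Genes were named by a rule fixed before the data were examined: the 10 tRNA genes with most reads in each library, the 5 highest and 5 lowest log2 ratios among genes with at least 100 reads over both libraries and at least 2 positions in one, tRNA genes without a read, each other RNA polymerase III locus, and the 10 outside positions with most reads in each library. Genes named for an insertion in 1 library alone, for orientation, for shared reads or for a box B score beyond these were chosen after their values were seen. The lists were amino acid families, intron-containing families, chromosomes, genes near an LTR, a sigma, another tRNA gene or a divergent coding gene. LTR and sigma lists used the deposited distance on either side, since its side could not be read. The list of genes near another tRNA gene counted placed starts only and is incomplete: it has 4 genes, while R64 has 12 with another within 500 bp. The 2 lists by distance to centromeres and chromosome ends were not run, because they need coordinates of the same build.

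Alternatives changed the read minimum, the window, the treatment of multiply aligned reads (each split equally over its alignments), the depth, the merging of neighbouring positions, the weighting and the treatment of sigma flanks. The interval and list computations were tested on simulated data for the comparison of the strains. Over 260 of 266 simulated genes, 96.5% of exact intervals held the planted ratio, and 20 genes planted at 2-fold had a median log2 ratio of 0.97 against a planted 0.97. The simulated reads varied by read counting alone, so this checked the computation and not the coverage in these data. Of 100 random lists 4 fell outside the central 95%, and of 100 lists raised by 1 SD 71 lay above it. All 532 planted insertions were returned at their planted distance, measured from the same gene starts, which checked the computation of distances only. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.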

Results

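The sites at which the yeast retrotransposon Ty3 inserted into the chromosomes of Saccharomyces cerevisiae were mapped in 2 strains, a wild type and an otherwise matching strain in which RAD52 was deleted. RAD52 encodes the main mediator of homologous recombination in yeast. A plasmid-borne Ty3 carrying HIS3 was switched on with galactose for 3 days at 24 °C, and cells that had lost the plasmid and kept HIS3 were selected. About 10000 colonies per strain were scraped and pooled, and the DNA next to the 3′ LTR of Ty3 was amplified by inverse PCR after digestion with 3 restriction enzymes. Each strain was represented by 1 library of 19-base reads. The wild type library held 3034624 reads that aligned to a single place and 185390 that aligned to several, and the rad52 deletion library held 3057512 and 188496. With 1 library per strain there was no replicate check, so differences between strains are given as values of these 2 libraries, without a test. RAD52 itself was not measured by this assay, so the strain labels could not be checked in the reads.

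Ty3 insertions lay almost entirely beside tRNA genes in both strains. Of 2362 insertion positions with at least 10 reads in the wild type library, 2209 lay within 100 bp of the first base of a tRNA gene, or 93.5% (Wilson 95% interval 92.5 to 94.4%). In the rad52 deletion library 1917 of 2076 positions did, or 92.3% (91.1 to 93.4%), so the intervals of the 2 libraries overlapped. These windows covered at most 0.457% of the aligned span of the chromosomes, and the positions were enriched in them at least 204-fold in wild type and 202-fold in the rad52 deletion. By reads, the share near tRNA genes was 94.5% in each library. Reads leaving the ends of Ty3 LTRs (sigma elements) listed in the authors' deposited table accounted for 4.38% of wild type and 4.26% of rad52 deletion reads, and with these left out the share near tRNA genes was 98.8% and 98.7%. PCR reads are not independent molecules, so all intervals cover counting error only.

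The insertions formed a narrow band just upstream of the tRNA genes. In the same orientation as the tRNA gene, the first flanking base was most often at −16 relative to the first base of the tRNA, and 39.1% of wild type and 38.8% of rad52 deletion reads in that orientation fell on this base. In the opposite orientation it was most often at −12, with 32.9% and 31.9% of reads. Placed on the upstream base of the 5 bp that Ty3 duplicates on insertion, both orientations had the same mode, −16, in both libraries. Within 2 bp of that mode lay 94.0% of tRNA-gene reads in each library, but only 64.4% of wild type and 68.8% of rad52 deletion positions near tRNA genes. Among the 256 wild type genes with at least 100 reads at their leading duplication, the median was −16 with quartiles of −17 and −15. The 20 bp upstream of the tRNA held 99.5% of tRNA-gene reads in each library, and only 0.0411% and 0.0332% of reads lay at or downstream of the first base. The same 5 bp were used in both orientations at 708 of 1501 duplications in wild type and at 610 of 1307 in the rad52 deletion.

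**Figure D1:**
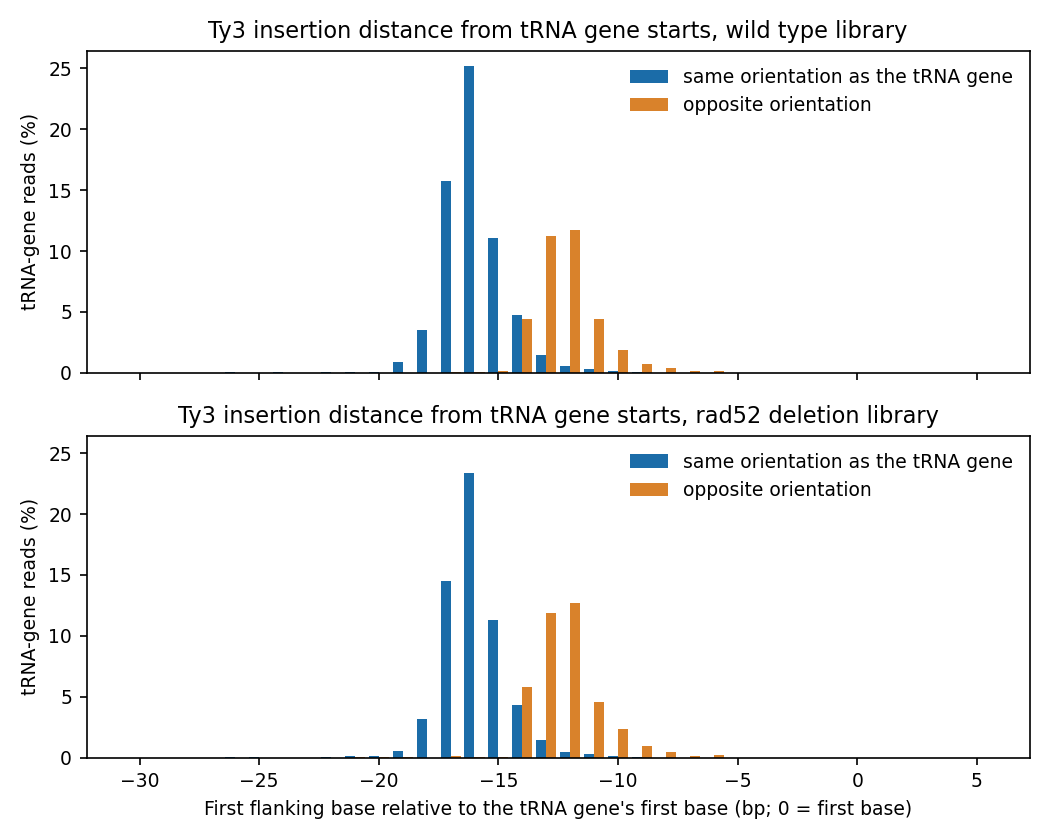
Percent of tRNA-gene reads (y axis) against the distance in bp of the first flanking base from the first base of the tRNA gene (x axis), for the wild type library (top) and the rad52 deletion library (bottom). Blue bars are Ty3 in the orientation of the tRNA gene, which peak at −16, and orange bars the opposite orientation, which peak at −12.

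Most tRNA genes were targets in both strains. Of the 275 nuclear tRNA genes listed for R64, at least 262 had an insertion position in wild type and 260 in the rad52 deletion, and 260 had one in both. Starts were placed for 266 genes, 265 of them through a cluster in the authors' deposited tables, so a share near 100% of the placed genes was fixed by how they were placed. The other 9 genes were not examined. The wild type library alone had a position at tK(CUU)G2 (42 reads against 9) and at tL(CAA)G2 (81 reads against 0). No position reached 10 reads at tY(GUA)J2, tV(AAC)L, tL(CAA)M or tD(GUC)N. Of these, tV(AAC)L had 14 reads in wild type and 17 in the rad52 deletion, and tD(GUC)N had 0 and 5. A count of 0 single-aligned reads allows up to 3. tL(CAA)M was the only gene without a single-aligned read in either library, but its flank is shared with tL(CAA)G2, and the authors' deposited table gives 46089 wild type and 57632 rad52 deletion reads that align to both.

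Reads were spread very unevenly over the targets. In wild type the median tRNA gene had 5000 reads at 8 positions, and 37 genes held 50% of the reads; in the rad52 deletion the median was 4752 reads and 33 genes held 50%. The leading gene in both libraries was tT(UGU)P, a threonine tRNA gene whose first base is at 744282 on chromosome XVI (sacCer2, as all coordinates here), with 94902 wild type and 116938 rad52 deletion reads. It was followed in both by the lysine gene tK(CUU)F on chromosome VI at 226747, with 82585 and 110176 reads, and the leucine gene tL(UAG)J on chromosome X at 617908, with 64315 and 79519. At tT(UGU)P the reads were spread over 22 wild type positions, whereas at tK(CUU)F 1 position, the + strand base 226761 with the flank GCTACTCGGCACTAAAAGA, held 76822 of the wild type reads. The phenylalanine gene tF(GAA)D was similarly concentrated, with 54140 of its 57923 wild type reads at base 1095472 of chromosome IV next to GAACTTCATGGGTGGTCTG. The other wild type genes among the top 10 were tG(GCC)G2 with 62398 reads, tL(GAG)G with 54889, tT(AGU)N2 with 52565, tS(AGA)G with 46675, tV(CAC)D with 44595 and tP(UGG)H with 43139. In the rad52 deletion, 7 of the top 10 were shared with wild type, and the others were tC(GCA)B with 56759 reads, tL(UAA)D with 49820 and tS(GCU)O with 46750.

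Reads were divided over the tRNA genes in nearly the same proportions in the 2 libraries. By positions per gene the Spearman rho was lower, at 0.834. Both libraries were amplified in the same way, so unequal amplification of the genes was not told apart from a shared use of targets. Across the 260 genes with at least 100 reads over both libraries, reads per gene correlated with a Spearman rho of 0.965 and a Pearson r of 0.961 on the log2 scale, which is a relation across genes and not across replicates. The share of tRNA-gene reads was within 2-fold at 237 genes, more than 2-fold higher in the rad52 deletion at 7 and more than 2-fold lower at 16. The SD of the log2 ratio over genes was 0.46 in the upper part of the genes by mean reads and 0.70 in the lower part. The lowest was at tD(GUC)I2, with a log2 ratio of −2.81 (exact 95% interval −3.29 to −2.36; 321 wild type and 46 rad52 deletion reads). It was followed by tK(UUU)L with −2.37 (1246 and 243 reads), tE(UUC)P with −1.82 (545 and 155), tD(GUC)O with −1.78 (378 and 111) and tS(AGA)A with −1.66 (11435 and 3657). The highest were tT(UGU)G2 with 1.86 (770 and 2817 reads), tA(UGC)G with 1.64 (1354 and 4262), tE(UUC)J with 1.42 (1474 and 3983), tP(UGG)L with 1.30 (3428 and 8527) and tR(ACG)D with 1.10 (1665 and 3601). Counted by positions instead of reads, the ratio changed sign at tD(GUC)O, tE(UUC)J and tR(ACG)D and came nearer 0 at the other 7, for example at −0.64 for tK(UUU)L, −0.53 for tS(AGA)A and 0.20 for tP(UGG)L. Some reads of tS(AGA)A and tT(UGU)G2 also aligned beside a tRNA gene of another amino acid, so the unique reads of both may be incomplete. tS(AGA)A shared 4486 wild type and 5637 rad52 deletion reads with tN(GUU)N1. tT(UGU)G2 shared 7 and 101 with a place listed under tY(GUA)J2. At tS(AGA)A the shared rad52 deletion reads outnumbered the 3657 unique ones, so its ratio of −1.66 is uncertain.

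**Figure D2:**
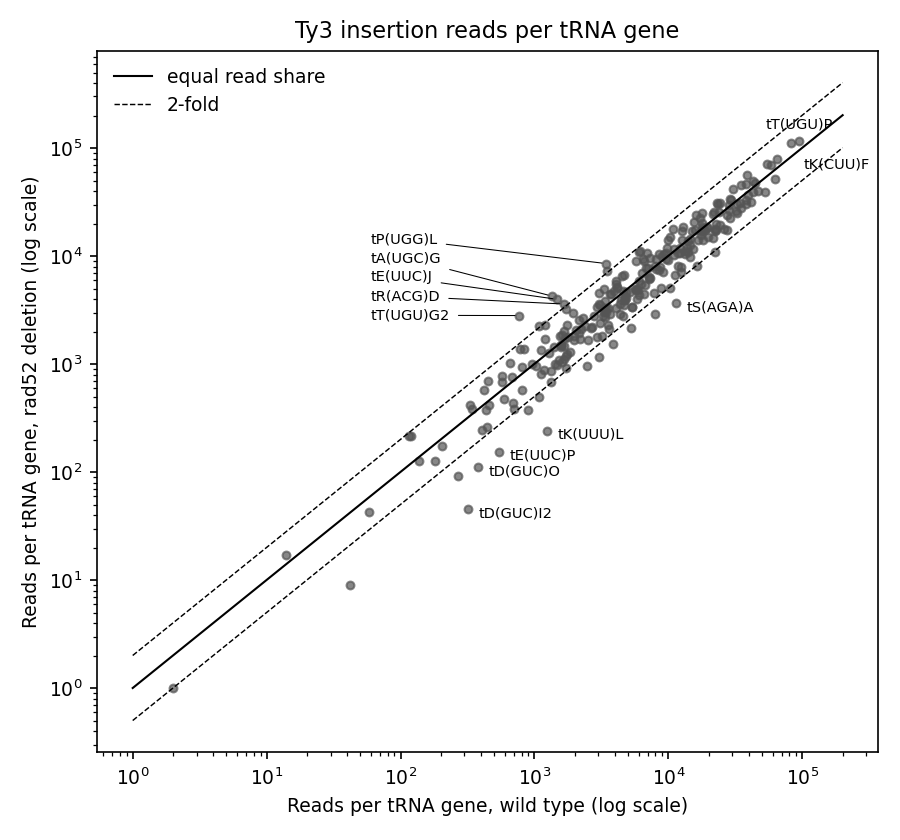
Reads per tRNA gene in the wild type library (x axis, log scale) against the rad52 deletion library (y axis, log scale), 1 point per gene with a read in both. The solid line marks equal shares and the dashed lines 2-fold differences; 237 of 260 genes with at least 100 reads lay within 2-fold, and the 5 highest and 5 lowest ratios and the leading genes are named.

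Genes of one amino acid, chromosome or setting did not move far as groups. Glycine genes had a median log2 ratio of −0.31 (21 genes, 5 higher in the rad52 deletion), at the 1.30 percentile of 10000 random lists matched on reads. Valine genes had −0.35 (17 genes, 2.27 percentile). The 32 genes with a divergent coding gene starting within 500 bp had 0.19, at the 99.3 percentile, with 21 of them higher in the rad52 deletion. These were 3 of 41 lists outside the central 95%, where chance gives 2.05. By positions none of the 3 stood outside, and the histidine list did, at the 98.8 percentile. The other amino acid lists ran from methionine, at the 4.64 percentile with a median of −0.47, to tryptophan, at 93.7. Chromosomes ran from VI, at the 3.58 percentile with −0.47, to XII, at 93.2. The intron-containing families stood at the 79.8 percentile with −0.09, genes with an LTR within 500 bp at 31.2 with −0.14, genes with a sigma within 50 bp at 24.5 with −0.18, and the 4 genes with another placed tRNA gene start within 500 bp at 11.7 with −0.35. Amino acid families differed much more in their share of single-aligned reads than the strains did. Unequal amplification of the families was not tested, and reads shared by gene copies were left out. Threonine genes, 6.02% of the genes, took 11.6% of wild type and 12.6% of rad52 deletion tRNA-gene reads, and leucine genes, 7.89% of the genes, took 12.5% and 14.1%. Glutamate genes, also 6.02% of the genes, took 2.17% and 1.87%, and tyrosine genes, 3.01% of the genes, took 0.915% and 0.906%.

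Insertion positions lay somewhat more often in the orientation of the tRNA gene. This was so for 1210 of 2209 positions in wild type, or 54.8% (Wilson 95% interval 52.7 to 56.8%), and for 1022 of 1917 in the rad52 deletion, or 53.3% (51.1 to 55.5%). The intervals treat positions as independent, but positions of the same gene share its skew, so they are too narrow. A position counts once however many insertions it holds. By reads the share was 64.3% and 60.3%. With every position of at least 1 read counted it was 51.9% (50.1 to 53.8%) and 50.9% (48.9 to 52.9%), so the interval of the rad52 deletion then included 50%. Reads of individual genes were strongly skewed toward or against the orientation of the gene, and the skew recurred in both libraries. Both libraries were amplified in the same way, so unequal amplification of the orientations was not told apart from a preference of Ty3. At tK(CUU)F 2.13% of wild type and 1.47% of rad52 deletion reads were in the orientation of the gene, and at tF(GAA)D 2.56% and 1.01%, whereas at tL(UAA)D 97.3% and 98.2% were and at tT(AGU)N2 94.9% and 96.4%. tT(UGU)P was near balance with 50.7% and 46.6%. In wild type 107 of 259 genes with at least 100 reads had over 90% of reads in one orientation, 77 of them that of the tRNA gene. Across 257 genes the orientation share of the libraries correlated with a Spearman rho of 0.970.

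Other genes transcribed by RNA polymerase III were also targets in both strains. Within 100 bp of its cluster, RPR1, the RNA of RNase P, had 9991 wild type and 10536 rad52 deletion reads, the cluster lying at 118118 to 118124 on chromosome V, 82 bp upstream of the annotated RNA by the authors' deposited table (−82). Counted likewise, SCR1, the RNA of the signal recognition particle, had 7225 and 5047 reads at 441977 to 441983 on chromosome V. SNR6, the U6 spliceosomal RNA, had 1502 and 2346 at 366231 to 366237 on chromosome XII. SNR52, a small nucleolar RNA, had 1349 and 906 at 431374 to 431379 on chromosome V, at −157. RNA170 had 311 and 953 at 667401 to 667407 on chromosome XIII. ZOD1, a locus bound by the RNA polymerase III machinery, had 4714 and 8472 at 91963 to 91970 on chromosome XIII, and 4708 and 8457 of these were on the + strand. A site between TIM21 and RPL26B on chromosome VII, at 555229, which the plan had equated with ZOD1 and which the authors' deposited table lists separately as iYGR033C, had 193 and 89 reads. Relative to all single-aligned reads, the rad52 deletion ran from 0.458 times wild type at iYGR033C (exact 95% interval 0.352 to 0.591) to 3.04 times at RNA170 (2.67 to 3.47), with RPR1 at 1.05 (1.02 to 1.08), SNR6 at 1.55, ZOD1 at 1.78, SCR1 at 0.693 and SNR52 at 0.667. Together these loci held 0.833% and 0.927% of reads. The authors' deposited tables list 0 clusters beside the 6 ETC loci, sites bound by TFIIIC without the polymerase. This does not show that Ty3 avoided them. The deposited clusters of single-aligned reads lack 91.8% of wild type and 92.7% of rad52 deletion positions outside RNA polymerase III genes. The alignments were not searched at the ETC loci. The RNA polymerase II controls SNR17A, TLC1, NME1, LSR1, SNR19 and SNR7 were not analysed here, because no coordinates on sacCer2 were used for them.

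A small set of insertion positions lay more than 500 bp from any placed RNA polymerase III gene. There were 98 in wild type, 4.15% of positions (Wilson 95% interval 3.42 to 5.03%), and 109 in the rad52 deletion, 5.25% (4.37 to 6.30%), with 0.326% and 0.356% of reads. These counts include flanks of sigma elements already in the genome, and 96 and 107 were left without those in the authors' deposited table. The positions outside were thin, with medians of 27 and 40 reads against 127 and 179 near tRNA genes. In both libraries 7 positions reached 10 reads. These include the sigma flanks at 712550 on chromosome VII and at 1023475 on chromosome IV (28 and 17 reads). The leading one was a + strand base on chromosome III at 169065, upstream of tQ(UUG)C (−696), with 1569 and 2409 reads. Inside the coding region of SCS3, on chromosome VII, Ty3 used 271599 on the + strand (835 and 188 reads) and 271603 on the − strand (265 and 285 reads). These are the ends of 1 duplication of 5 bp. Close by, at 271597, which was not assigned to a coding gene, the rad52 deletion had 553 reads where wild type had 0. Inside YIL100C-A, on chromosome IX, 177569 had 324 and 69 reads on the + strand. Both coding regions had a box B score of 1 in the authors' deposited table, the highest value there, which 32 of 296 clusters share (box B is an internal promoter element of tRNA genes). The leading site at 169065 had 0.825, and the remaining outside clusters, in YJL206C and YCG1, had 0.825 and 0.826. The sigma flank at 712550 on chromosome VII had 1106 and 203 reads.

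Most of the other leading positions were in 1 library alone. Wild type had 661 reads at 242011 and 410 at 225442 on chromosome V, 436 at 18471 on chromosome XI, 234 at 828150 on chromosome XII and 196 at 560025 on chromosome XIII, with 0 at each in the rad52 deletion. The rad52 deletion had 512 reads at 471087 on chromosome X, 336 at 749895 on chromosome XIV, 278 at 629954 on chromosome XI, 248 at 193398 on chromosome V, 231 at 682024 on chromosome II and 220 at 504961 on chromosome IV, with 0 at each in wild type. The count outside depended on the read minimum, with 15 wild type and 24 rad52 deletion positions at 100 reads and 527 and 407 at 1 read. The share outside was higher in the rad52 deletion at 100 reads (1.21% and 1.94%) but lower at 1 read (15.4% and 14.4%). The starts of 9 of the 275 nuclear tRNA genes listed for R64 were not placed, so some of these positions may lie beside one, and positions outside the deposited clusters were not assigned to coding genes.

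**Figure D3:**
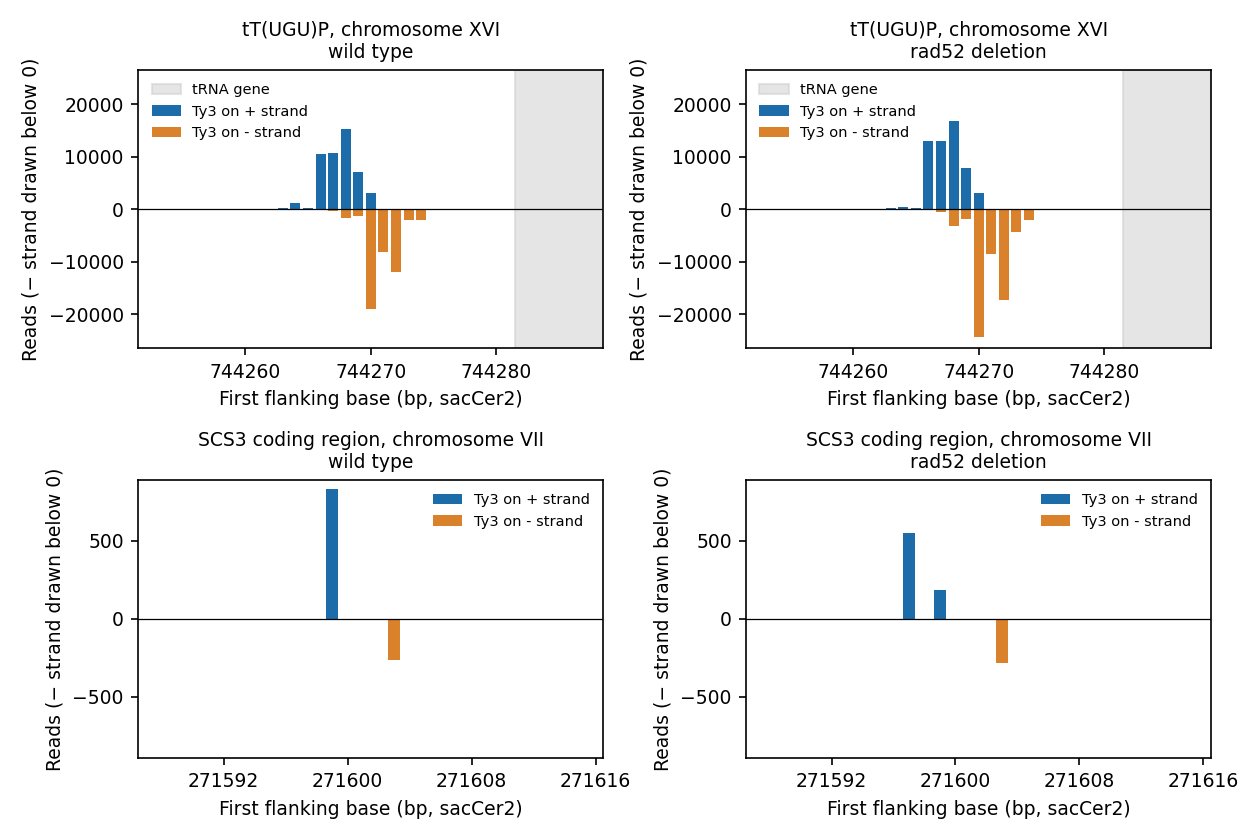
Reads at each first flanking base (x axis, bp on sacCer2) at tT(UGU)P (top, grey marks the tRNA gene) and within SCS3 (bottom), in wild type (left) and the rad52 deletion (right), with Ty3 on the + strand drawn upward and on the − strand downward (y axis, reads). At tT(UGU)P many neighbouring bases were used in both orientations, and in SCS3 bases 271599 and 271603 were used in both libraries. Base 271597, which was not assigned to a coding gene, had 553 reads in the rad52 deletion and 0 in wild type.

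Reads that aligned to several places came mainly from 5S rRNA genes and tRNA gene copies. The 5S genes (RDN5), also transcribed by RNA polymerase III, took 65833 wild type and 65048 rad52 deletion reads, or 35.5% (Wilson 95% interval 35.3 to 35.7%) and 34.5% (34.3 to 34.7%) of the multiply aligned reads. At RDN5-1, 74.9% and 76.0% of these were on 1 duplication starting at 459672 on chromosome XII. A further 53.4% and 59.9% aligned only beside tRNA genes, led by the pair tL(CAA)G2 and tL(CAA)M, then tK(UUU)O and tK(UUU)P with 22183 and 21376 reads in the authors' deposited table. The copies cannot be told apart with 19 bases. Reads with no alignment at a 5S gene or beside a tRNA gene made up 10.9% and 5.44%.

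The authors' deposited table of single-aligned clusters holds 296 clusters with a median width of 8 bp, 263 of them within 20 bp of a tRNA gene start. Its clusters held 98.5% of wild type and 98.7% of rad52 deletion single-aligned reads. The read numbers of all 296 clusters were recovered exactly from the alignments when a coordinate needed at least 5 reads on a strand in each of the 2 libraries, the strands not having to agree, against 259 at 4 reads and 262 at 6. Coordinates that did not reach this in both libraries are therefore absent from that table, among them 91.8% of the wild type and 92.7% of the rad52 deletion positions outside RNA polymerase III genes. The table leads, as the alignments did, with tT(UGU)P, and its largest cluster has 94451 wild type and 116938 rad52 deletion reads.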

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

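The groups of reads in the next paragraph lie in multiply aligned or mitochondrial data. The ratios of the strains per tRNA gene did not use them, and each group exceeds the 3 reads that a count of 0 allows. For the patterns weighed here, the tests of read counting, of colony sampling and of the upstream peaks were chosen after the result was seen.

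Reads at the inner edge of the 5′ LTR of both full-length Ty3 elements, at 707539 on chromosome VII (YGRWsigma4) and at 205557 on chromosome IX (YILWsigma1), numbered 18424 in wild type and 5711 in the rad52 deletion, or 9.94% and 3.03% of the multiply aligned reads. A second group of 339 wild type and 2663 rad52 deletion reads aligned to 30 places on 12 chromosomes, 27 of them 361 to 362 bp from a delta element, the LTR of Ty1 and Ty2, and its share of multiply aligned reads in the rad52 deletion was 7.73 times that in wild type. The origin of these reads was not resolved, so this is not a difference in known insertions. A further group of 3334 wild type and 2015 rad52 deletion reads lay at the 3′ end of tR(UCU)B, tR(UCU)D, tR(UCU)J1 and tR(UCU)J2, on chromosomes II, IV, X and X. The 3′ end of tR(UCU)M2 had 1148 and 822 multiply aligned reads, and 920 and 645 were shared by 6 further tR(UCU) genes. R64 has 4 pairs of tRNA genes at most 20 bp apart, also on chromosomes II, IV, X and X, so the first of these groups was not told apart from insertions upstream of an adjacent tRNA gene. The mitochondrial chromosome had 18 single-aligned reads in wild type and 13 in the rad52 deletion, with 0 positions of 10 reads.

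Single-base peaks stood 355 to 361 bp upstream of 15 tRNA genes, with 131909 wild type and 129952 rad52 deletion reads. The highest in wild type were at tY(GUA)D (37772 and 31377 reads in the authors' deposited table), tK(UUU)P (21668 and 21982) and tA(UGC)O (15568 and 13465). Priming from Ty3 LTRs already in the genome may account for the peaks: 100% of them lay within 5 bp of the end of a sigma element, on the strand leaving it. New insertions at a further site upstream are argued against for these peaks. All 15 deposited clusters in this range were a single base wide and lay at such an end. The 296 single-aligned clusters of the deposited table had a median width of 8 bp, and 36 of the 296 were a single base wide. Bases with fewer than 5 reads in either library are absent from that table. The strands add nothing to this. Although 0% of the peaks had reads on both strands, the flanks of both orientations lie 4 bp apart, so a single-base peak could not hold both and the test was void.

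Read numbers at single positions differed between the libraries far more than read counting allows. Over 232 positions with a mean share of at least 0.1% the log2 ratios had an SD of 0.54, and 200 draws of the observed number of reads gave at most 0.031. Draws of 10000 events per library, the approximate number of colonies, gave 0.41 to 0.58, so sampling of colonies is a candidate explanation, with unequal amplification untested. An effect of the RAD52 deletion on single sites cannot be told apart from this, because there is 1 library per strain.

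Positions more than 500 bp from RNA polymerase III genes were mostly in 1 library. Misread copies of abundant reads are argued against: 0.493% of 203 positions left without the sigma flanks (Wilson 95% interval 0.087 to 2.74%), fewer than the 5% set before the test, had a read within 2 mismatches of a single-aligned read 100 times more abundant. The share of such positions in the rad52 deletion was 1.27 times that of wild type with sigma flanks counted, but 0.93 times at 1 read per position, so the direction depended on the read minimum. Whether the deletion changes it cannot be told apart from chance between pools, because there is 1 library per strain, and other sources such as joined fragments in the PCR were not tested.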

How the results depend on the processing

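No paired analysis was possible because each strain had 1 library and no comparison came from a test. The alternatives with at least 5 reads in both libraries, with sigma flanks left out of the read share and with chromosome X starts moved by 1 bp were chosen after seeing the data. Matching the flanks to a genome independently was not run. Values are given for wild type, then the rad52 deletion, and where no cause is named the cause was not tested.

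The number of tRNA genes with an insertion ranged from 251 to 264, but could hardly move, because nearly all genes counted were placed through deposited clusters. Thinning removed 22888 rad52 deletion reads and no wild type reads, too few to test depth, and changed no value. The share of positions near tRNA genes was 82.0% and 82.9% at 1 read per position, 96.7% and 95.6% at 100 reads, 87.1% and 87.5% in a 20 bp window, 90.4% and 89.1% with multiply aligned reads, 87.7% and 86.4% after merging within 2 bp, which joins positions in the dense clusters, and 97.4% and 97.3% with 5 reads in both libraries. The share of reads was 94.1% and 94.0% at 20 bp, 98.8% and 98.7% at 500 bp, which takes in the sigma flanks, 92.1% and 92.5% with multiply aligned reads, which brings in the 5S genes, and 98.8% and 98.7% without sigma flanks. The share in the orientation of the tRNA gene was 51.9% and 50.9% at 1 read, 58.4% and 57.3% at 100 reads, 64.3% and 60.3% by reads, and 56.9% in wild type with multiply aligned reads; at 1 read the rad52 deletion interval (48.9 to 52.9%) included 50%. Positions outside RNA polymerase III genes numbered 527 and 407 at 1 read, 15 and 24 at 100 reads, 177 and 188 with multiply aligned reads and 8 and 9 with 5 reads in both libraries, where the added filter removes coordinates of 1 library by its construction.

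The opposite-orientation mode moved from −12 to −16 in both libraries on the upstream base of the duplication, by construction, and no mode moved with each position counted once or with chromosome X starts shifted. The Spearman rho over genes was 0.834 by positions and 0.944 without each gene's leading position, and the number of genes within 2-fold stayed within 1.5 times. By positions the log2 ratio was 0.20 for tD(GUC)O, −0.058 for tR(ACG)D and −0.21 for tE(UUC)J, each opposite in sign to that by reads. The other named genes kept their sign in both settings, but of 20 values for named genes 14 moved without a change of sign: by positions tK(UUU)L went from −2.37 to −0.64 and tP(UGG)L from 1.30 to 0.20, and without its leading position tT(UGU)G2 went from 1.86 to 0.87. By positions 1 list stood outside the central 95% instead of 3.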

Other observations

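Existing Ty3 LTRs with reads at their ends were spread over 17 clusters of the authors' deposited table. Their reads moved in both directions between the libraries. YGRWsigma5, the far LTR of a full-length element on chromosome VII, had 1106 wild type and 203 rad52 deletion reads, YLRWsigma3 beside tA(AGC)L 473 and 98, YDRWsigma2 beside tI(AAU)D 944 and 635, and YPRWsigma4 beside tI(AAU)P2 761 and 510. YPRWsigma2 beside tK(UUU)P had 21668 and 21982, and YERCsigma1 beside tQ(UUG)E1 12099 and 18308.

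The deposited table of single-aligned clusters has one beyond the 3′ end of tW(CCA)G1 on chromosome VII, at 287306 to 287311, with 88 wild type and 136 rad52 deletion reads and a deposited distance of +45. Within 100 bp of a tRNA gene start, 19 wild type and 13 rad52 deletion positions lay at or downstream of the first base. More than 500 bp from an RNA polymerase III gene, 5 deposited clusters were not at a listed sigma element. Those in YJL206C (19 and 18 reads) and YCG1 (13 and 5 reads) had box B scores of 0.825 and 0.826. The most used of the 5, at 169065 on chromosome III (1569 and 2409 reads), also had 0.825, against 1 in SCS3 and YIL100C-A. The median score was 0.959 over 263 clusters at tRNA gene starts and 0.834 over the sigma flanks. These clusters were singled out after their values were seen.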
